A study of Mus musculus with 8 samples.

How the data were processed

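Gene expression was measured by RNA sequencing in mouse bone marrow derived macrophages, cells grown from marrow under conditions that favour the macrophage lineage, at day 7 of differentiation. The series compared wild-type (WT) cultures with cultures labelled as Baf60a knockout (Baf60a KO), with 4 libraries in each group. Baf60a is the protein name of Smarcd1, a subunit of the SWI/SNF (BAF) chromatin remodelling complexes. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate mice or separate cultures, so p-values measure the spread between these libraries, part of which could be technical. The series title names C57 mice. The part of Smarcd1 that was deleted and the way of deletion are not given in the sources used here.

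Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with the NEBNext Ultra RNA kit, and an Illumina NovaSeq gave paired reads of 51 bp; only an average depth over samples is stated. Per the submitters' processing notes, bcl2fastq, Salmon 1.2.0 and the genome build mm10 were used. The transcript annotation, the mapping options of Salmon and the way transcripts were summed to genes are not given in the sources used here. The deposited table holds 1 TPM value (transcript abundance corrected for length and scaled to the same total in every library) per gene and library, given by the authors to 2 decimals and with no unit in the header. The unit was read from the values, since every library summed to 1000000 within rounding, and low values were not whole multiples of a common step. TPM is scaled within each library, so a large change in some transcripts moves the values of all others. It keeps no read depth, so no counting interval can be given and a value of 0 has no detection limit. The design fixed beforehand expected counts and named a log-scale test for a table without them; that test was used.

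The table lists 55421 gene identifiers, of which 55154 matched a symbol by Ensembl identifier and 267 did not; the unmatched ones held between 0.0309% and 0.0451% of the TPM of a library. Symbols, gene types and coordinates came from GENCODE M21, which is on the same assembly as mm10. No pair of columns was identical. Genes with TPM over 1 in at least 4 libraries were tested, which left 13933. Values were analysed as log2(TPM + 1), a scale that understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, group as the only term, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at adjusted p under 0.05, and "rose" and "fell" are used of called genes. Fold changes are Baf60a KO minus WT on the log2 scale.

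Before the data were examined, 37 gene lists were fixed: pathways, cell type markers and signs of RNA quality. Lists with at least 5 tested members (31 of them) were tested against all other genes with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were alternatives. Genes named in the text follow a rule fixed at the same time: Smarcd1, Smarcd2, Smarcd3 and Lyz2; the 8 largest rises and 8 largest falls among called genes with mean TPM over 2, groups that do not overlap and an official symbol; up to 4 called members of each list with the smallest adjusted p, and, where fewer than 2 were called, the most abundant others as values; and Atf3, Tnf, Il1b and Il6. The rule gave 111 genes, of which some are not reported here.

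The steps were tested on simulated data with the means and residual spread of the 13933 genes and 200 changed genes. At a simulated fold of 1.25, 32.8% of changed genes were recovered. At a fold of 1.5 this was 65.7%, and at a fold of 2 it was 83.3%. False calls made up 4.7% of calls, no call was made with nothing changed, and camera called the 1 list that was moved and 0 of the others. Simulated genes varied independently and the simulated lists were random genes. False list calls by camera among correlated genes were thus not tested, and estimated correlations in the real lists reached 0.737 (mitochondrially encoded genes). Alternatives covered the pseudocount, the filter on low values, the variance model, the replicate number as a block and leaving out each library. After seeing the data, other scalings of TPM, a stricter filter, library weights, a pseudogene covariate and a fit without WT replicates 3 and 4 were added. Alternatives that need read counts were not run. Transcript similarity was measured with BLAST 2.17.0 on the GENCODE M21 transcripts.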

Results

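RNA was profiled in 8 libraries of mouse bone marrow derived macrophages at day 7 of differentiation, 4 from WT and 4 from Baf60a KO cultures. The comparison asks which transcripts differ in cultures labelled as knockout for Baf60a, which Smarcd1 encodes. Values are TPM, and each library summed to 1000000, so the read depth of single libraries is unknown. Between 13727 and 14027 genes had TPM over 1 per library. Protein-coding genes held 87.4% ± 2.93 of TPM in WT (SD, n = 4) and 89.0% ± 0.585 in KO. Processed pseudogenes held 12.004% in WT replicate 3 and 12.25% in WT replicate 4, against 6.78% to 8.38% in the other libraries. The group means of this share were 9.67% ± 2.87 and 7.90% ± 0.377 and did not differ in an exact two-sided permutation test (p = 0.4). The first principal component, with 30.0% of the variance, placed WT replicates 3 and 4 at 20.1 and 22.2 and WT replicate 1 at -26.0, with the KO libraries between. The second component, with 21.2%, separated the groups, with WT between 6.79 and 14.9 and KO between -15.5 and -9.15.

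Smarcd1 (chromosome 15, 99702129 to 99713991, build mm10) was lower in all 4 KO libraries than in any WT library. Its TPM was 16.25, 14.29, 14.76 and 14.01 in WT replicates 1 to 4, and 10.79, 10.27, 10.85 and 9.91 in KO. The log2 fold change was -0.47 (SE 0.061, limma adjusted p = 0.00756), and the ratio of mean TPM, KO over WT, was 0.705. A gene-level TPM does not show whether the remaining transcripts lack the deleted part, or which cells of the cultures carry them. Whether the deletion was complete was not tested. The paralogs did not pass the test. Smarcd2 was at 36.2 ± 1.70 TPM in WT and 39.1 ± 1.94 in KO (adjusted p = 0.269), and Smarcd3 at 8.68 ± 0.588 and 9.81 ± 0.545 (adjusted p = 0.189). Of 24 other BAF subunits tested, Dpf2 fell, from 95.7 ± 7.06 to 79.3 ± 4.33 TPM (log2 fold change -0.27, adjusted p = 0.0453), and 23 did not pass, including Smarce1 at 102.0 ± 10.01 and 90.01 ± 2.82 TPM. With adjustment over the list alone 0 members passed. Camera did not call the list (adjusted p = 0.782), whose median (0.03) and mean (0.01) were above 0 while its test pointed down, since it compares the list with all other genes. The Dpf2 call ended without any 1 of 7 of the 8 libraries, with adjusted p up to 0.126 without KO replicate 4.

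**Figure D1:**
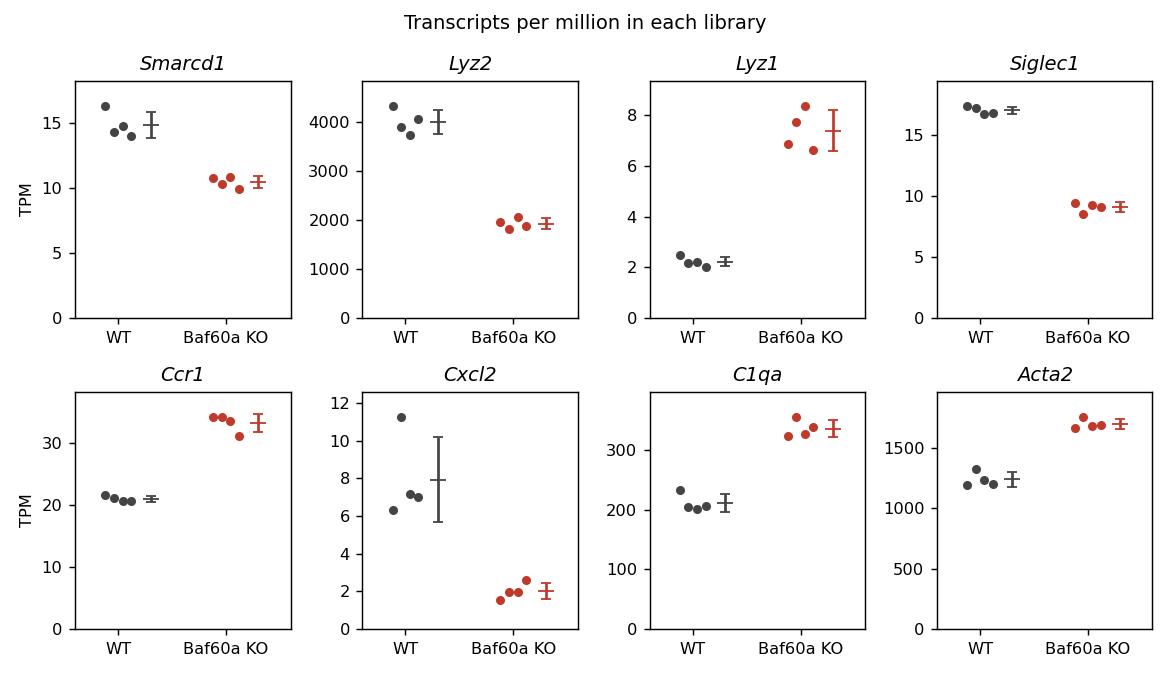
TPM (vertical axes, linear from 0) of 8 genes in each WT (grey) and Baf60a KO (red) library, with the group mean and SD beside the points. Smarcd1 lies between 9.91 and 10.85 in KO and between 14.01 and 16.25 in WT, and in each panel the KO libraries lie apart from the WT libraries.

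Of 13933 genes tested, 782 (5.61%) were called, of which 613 rose and 169 fell in Baf60a KO. Most changes were small. The median absolute log2 fold change of called genes was 0.34, and 11 reached 1. The groups did not overlap for 2204 genes (15.8%), where chance gives 2.86%. Lyz2 (chromosome 10, 117277331 to 117282321), the main lysozyme of macrophages, fell from 3993 ± 248 to 1927 ± 110 TPM (log2 fold change -1.05, SE 0.058, adjusted p = 0.000195). Its neighbour Lyz1 (chromosome 10, 117287797 to 117292868) rose from 2.23 ± 0.190 to 7.38 ± 0.792 TPM (log2 fold change 1.37, adjusted p = 0.000195). The transcripts of both genes are 95.8% identical over 1264 bases, so reads could be split between them. Among called genes with an official symbol, mean TPM over 2 and groups that did not overlap, falls were found in Cxcl2, a neutrophil chemokine (log2 fold change -1.55), Lyz2, F7, coagulation factor VII (-0.93), Clec10a, a macrophage lectin (-0.89), and Ffar2, a receptor of short-chain fatty acids (-0.88). Siglec1, the sialic acid receptor CD169 (-0.83), and Pla2g2e, a secreted phospholipase (-0.80), also fell. After Lyz1, the largest rises among such genes were in Thy1, a surface protein of stromal cells and lymphocytes (1.06), Fcna, a ficolin (1.004), and Igfbp6 (0.98). Cnn1, smooth muscle calponin (0.96), Ccn5 (0.81), Arap3 (0.80) and Igfbp3 (0.79) followed. Thy1 and Cnn1 are also members of the mesenchymal list given further on, and which cells carry these rises was not tested. Adjusted p ranged from 0.000195 to 0.0285 over these 15 falls and rises, whose full separation between the groups was a condition of their choice.

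The split of rises and falls depended on the scaling. Median-of-ratios scaling of TPM gave 503 rises and 406 falls, quantile normalization 440 and 254, and TPM rescaled over protein-coding genes 842 and 484. Without WT replicates 3 and 4, 201 genes rose and 171 fell. The count also fell with single libraries left out, to 447 without WT replicate 2, 229 without WT replicate 4, and 228, 217, 212 and 156 without KO replicates 1, 2, 3 and 4. Ffar2, Pla2g2e, Arap3 and Igfbp3 lost the call in at least 1 of these fits, with adjusted p up to 0.0727, 0.0869, 0.0707 and 0.0734, each without KO replicate 4, and the other 11 genes did not with 1 library left out. Igfbp6 lost its call without WT replicates 3 and 4 (adjusted p = 0.0537) and with the replicate number as a block (0.0679).

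**Figure D2:**
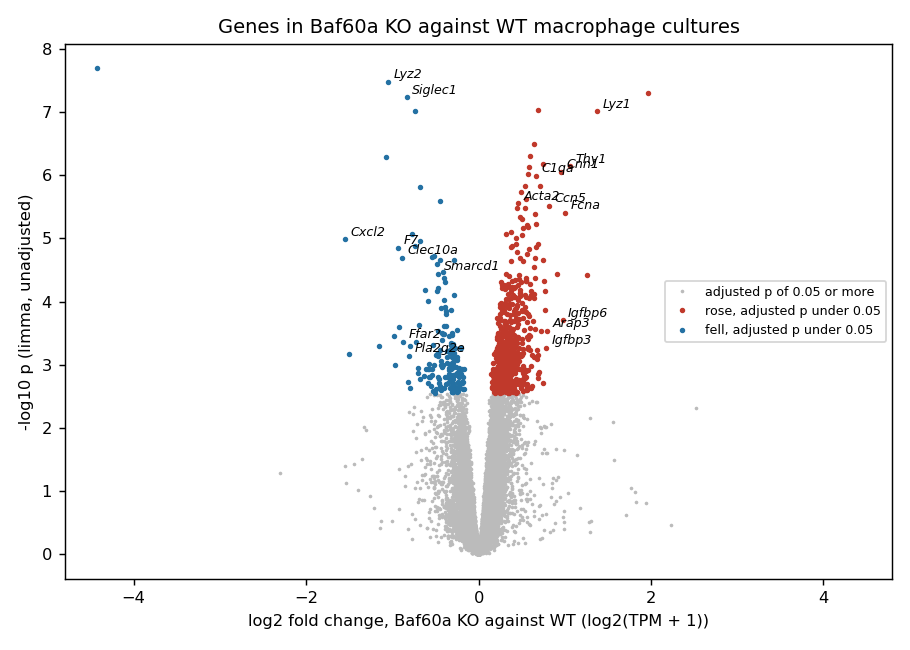
Log2 fold change of Baf60a KO against WT (horizontal axis, on log2(TPM + 1)) and -log10 of the unadjusted limma p (vertical axis) for the genes tested. Red points are the 613 genes that rose, blue points the 169 that fell and grey points the rest.

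Of the 31 lists tested, camera called 12, of which 7 were higher and 5 lower in Baf60a KO than other genes. With an estimated inter-gene correlation 0 of the 12 kept adjusted p under 0.05, and 1 of them, the inflammatory list, had an unadjusted p under 0.05 (p = 0.0202). Fry called 7 of the 31 by direction and 23 for change in either direction. Of the 12, the inflammatory, lysosome, efferocytosis, matrix, adhesion and stromal lists were called by directional fry, and the other 6 were not (adjusted p from 0.163 to 0.274). In other splits of the 8 libraries camera called up to 10 lists.

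**Figure D3:**
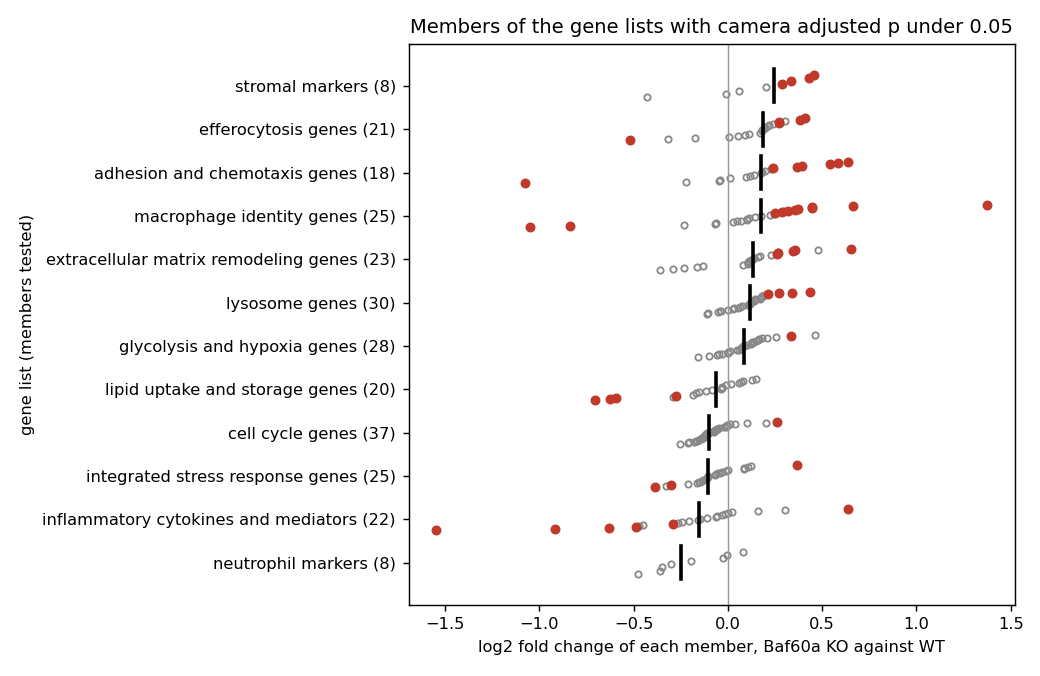
Log2 fold change (horizontal axis) of each tested member of the 12 lists called by camera. Filled red points are members with adjusted p under 0.05, open points the others, and black bars the list medians, which run from -0.25 in neutrophil markers to 0.25 in stromal markers.

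Of 25 macrophage identity genes tested in Baf60a KO against WT, 9 rose, 2 fell and 14 did not pass; adjusted over the list alone, 14 rose and 2 fell. C1qa, a chain of complement C1q, rose from 212 ± 14.8 to 336 ± 14.5 TPM (log2 fold change 0.66, SE 0.056, adjusted p = 0.000899). Lyz2 and Siglec1 were the members that fell, Siglec1 from 17.0 ± 0.290 to 9.11 ± 0.408 TPM (log2 fold change -0.83, SE 0.050, adjusted p = 0.000195), and Lyz1 was among those that rose. The median log2 fold change of the list was 0.17 (camera adjusted p = 0.00108, adjusted p = 0.724 with an estimated correlation, and 0.163 by directional fry). Lysosome genes rose in 4 of 30 members and fell in 0, and 26 did not pass, with 11 rises adjusted over the list alone. Ctsh, a cathepsin, rose from 181 ± 11.6 to 229 ± 4.35 TPM (log2 fold change 0.34, adjusted p = 0.00994). Gusb (0.27) and Ctsb (0.21) also rose, and camera gave adjusted p = 0.000529 (adjusted p = 0.646 with an estimated correlation). Gusb and Ctsb lost the call without single libraries, with adjusted p up to 0.0915 and 0.124 without KO replicate 4, and Ctsb also under median-of-ratios scaling and quantile normalization. Of 8 stromal markers tested, given further on, 4 rose in the same comparison (camera adjusted p = 0.00275; adjusted p = 0.646 with an estimated correlation).

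Receptors for uptake and migration moved in both directions. Of 21 efferocytosis genes, 4 rose, 1 fell and 16 did not pass; adjusted over the list alone, 13 rose and 3 fell (camera adjusted p = 0.00400; adjusted p = 0.646 with an estimated correlation). The bridging molecules Gas6 (from 108 ± 5.88 to 143 ± 9.95 TPM, log2 fold change 0.41) and Mfge8 (0.27) and the integrin Itgb5 (0.27) rose, whereas the scavenger receptor Stab1 fell from 66.2 ± 4.12 to 46.0 ± 2.91 TPM (log2 fold change -0.52, adjusted p = 0.00503). Of 18 adhesion and chemotaxis genes, 6 rose, 1 fell and 11 did not pass; adjusted over the list alone, 9 rose and 2 fell (camera adjusted p = 0.00421; adjusted p = 0.646 with an estimated correlation). Ccr1 rose from 21.02 ± 0.514 to 33.3 ± 1.44 TPM (log2 fold change 0.64, SE 0.046, adjusted p = 0.000566). The anaphylatoxin receptor C3ar1 (0.54) and the integrin Itgb7 (0.59) also rose. Mfge8 lost the call without KO replicate 4 (adjusted p = 0.0540) and Itgb5 in 5 of the leave-one-out fits (adjusted p up to 0.0768 without KO replicate 4). Gas6 and the adhesion list (adjusted p = 0.0549) were not called without WT replicates 3 and 4. In the same cultures 4 of 8 stromal markers, given further on, also rose. Which cells carry the efferocytosis and adhesion transcripts was not tested.

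Of 22 inflammatory cytokines and mediators tested, 5 fell, 1 rose and 16 did not pass; adjusted over the list alone, 8 fell and 1 rose. Cxcl2 fell from 7.94 ± 2.24 to 2.02 ± 0.443 TPM (log2 fold change -1.55, SE 0.17, adjusted p = 0.00359). Cxcl1, another neutrophil chemokine, fell from 1.92 ± 0.410 to 0.553 ± 0.272 TPM (log2 fold change -0.92), and the monocyte chemokine Ccl7 from 38.01 ± 3.06 to 26.8 ± 0.803 TPM (-0.49). Ccl2, the neighbouring monocyte chemokine, rose from 19.5 ± 2.13 to 30.9 ± 2.09 TPM (log2 fold change 0.64, adjusted p = 0.00624). The list median was -0.16 (camera adjusted p = 0.000110; adjusted p = 0.625 with an estimated correlation). Tnf was at 17.6 ± 3.48 TPM in WT and 14.4 ± 1.45 in KO and did not pass (adjusted p = 0.283). Il1b, at 0.270 ± 0.0876 and 0.415 ± 0.355 TPM, and Il6, at 0.315 ± 0.105 and 0.498 ± 0.0793 TPM, were too low to be tested. Cxcl1 lost the call without KO replicate 1 (adjusted p = 0.05005) and without KO replicate 2 (adjusted p = 0.0570), in 2 of the 4 leave-one-out fits that tested it, since it passed the filter through the 4 WT libraries alone.

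Genes of the integrated stress response, a programme driven by ATF4, were called lower as a list by camera (25 tested, median log2 fold change -0.10, adjusted p = 0.000110; adjusted p = 0.646 with an estimated correlation, and 0.166 by directional fry). Of these, 2 fell, 1 rose and 22 did not pass; adjusted over the list alone, 6 fell and 1 rose. Ppp1r15a, a phosphatase subunit that reverses the response, fell from 86.6 ± 4.57 to 66.2 ± 4.44 TPM (log2 fold change -0.38, adjusted p = 0.0125), and Psat1, an enzyme of serine synthesis, fell from 133 ± 9.25 to 108 ± 3.73 TPM (-0.30). Atf3, a stress-induced transcription factor, rose from 235 ± 21.7 to 302 ± 5.31 TPM (log2 fold change 0.37, SE 0.064, adjusted p = 0.0210). The Atf3 call ended without each KO replicate in turn, and that of Psat1 in 6 leave-one-out fits, with adjusted p up to 0.0707 and 0.0712. Immediate early genes went both ways: of 25, Egr1 (log2 fold change -0.53), Ier2 (-0.31) and Fosl1 (-0.43) were among 4 that fell, Dusp1 was the 1 that rose (0.30), and 20 did not pass. Adjusted over the list alone 4 rose and 5 fell, and the median was 0.02 and the mean -0.05 (camera adjusted p = 0.342). These 4 calls were lost in 4 to 7 of the leave-one-out fits. The unfolded protein response list was not called (adjusted p = 0.696): of 21 members Sdf2l1 rose (0.22), also adjusted over the list alone, while the chaperone Hspa5 was at 979 ± 65.9 and 954 ± 19.5 TPM. Sdf2l1 lost its call in 4 leave-one-out fits (adjusted p up to 0.0756 without KO replicate 4) and without WT replicates 3 and 4 (0.0620).

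Interferon-stimulated genes were not called as a list (34 tested, camera adjusted p = 0.960). Oasl1 fell from 11.2 ± 0.949 to 7.71 ± 0.289 TPM (log2 fold change -0.48, adjusted p = 0.00942), which also passed over the list alone, and 33 did not pass, including Bst2 at 780 ± 48.9 and 791 ± 96.1 TPM. Of 10 alternative activation genes, 2 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.257). Clec10a fell from 9.27 ± 1.18 to 4.55 ± 0.629 TPM (log2 fold change -0.89, adjusted p = 0.00503) and Cd200r1, an inhibitory receptor, from 101 ± 10.4 to 75.2 ± 3.27 TPM (-0.42). Il4ra, the receptor chain for IL-4, rose from 41.1 ± 0.868 to 46.6 ± 1.02 TPM (0.18, adjusted p = 0.0356), a call that ended in all 8 leave-one-out fits, and Cd200r1 lost its call in 3 (adjusted p up to 0.0734). Of 11 antigen presentation genes 0 passed by limma, and 1 rose adjusted over the list alone (camera adjusted p = 0.250); H2-DMb1 was at 35.7 ± 4.14 and 43.8 ± 0.692 TPM and Rfxap at 31.3 ± 2.17 and 31.1 ± 3.08. Without WT replicate 1 this list was called higher (adjusted p = 0.0264).

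Of 20 lipid uptake and storage genes tested, 4 fell, 0 rose and 16 did not pass, with the same counts adjusted over the list alone. Plin2, which coats lipid droplets, fell from 1572 ± 125 to 1045 ± 116 TPM (log2 fold change -0.59, SE 0.088, adjusted p = 0.0112), and Mgll, a monoglyceride lipase, from 19.4 ± 2.06 to 12.2 ± 1.116 TPM (-0.63, adjusted p = 0.00933). The scavenger receptor Marco (-0.71) and the lipase inhibitor Angptl4 (-0.27) were the others. The list median was -0.06 (camera adjusted p = 0.00191; adjusted p = 0.646 with an estimated correlation, and 0.272 by directional fry). Marco and Angptl4 each lost the call in 7 of the 8 leave-one-out fits (adjusted p up to 0.0941 and 0.0992).

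Of the other metabolic lists, camera called 1. Fry called change in either direction for cholesterol synthesis (adjusted p = 2.26e-06), liver X receptor targets and fatty acid oxidation (5.94e-06 each), NRF2 targets (5.81e-05), glycolysis and hypoxia (0.00417) and oxidative phosphorylation (0.0269), a test that does not compare a list with other genes. Liver X receptor targets (14 tested, camera adjusted p = 0.977, median 0.03 and mean -0.01) held 2 rises, Scd2, a fatty acid desaturase (from 33.2 ± 2.15 to 43.2 ± 1.57 TPM, log2 fold change 0.37, adjusted p = 0.0106), and Smpdl3a (0.27), also adjusted over the list alone. Cholesterol synthesis genes (24 tested, adjusted p = 0.960) held 1 rise, in Tm7sf2 (0.27), and adjusted over the list alone 3 rose and 2 fell; Srebf2 was at 28.8 ± 2.08 and 29.7 ± 1.97 TPM. NRF2 targets (22 tested, adjusted p = 0.571) held 2 rises, G6pdx, the first enzyme of the pentose phosphate pathway (0.26, adjusted p = 0.00838), and Prdx1 (0.24), and 3 rises adjusted over the list alone. Glycolysis and hypoxia genes (28 tested) were called higher by camera (adjusted p = 0.0165; adjusted p = 0.779 with an estimated correlation, and 0.193 by directional fry), with 1 member past the threshold, the lactate transporter Slc16a3 (from 108 ± 8.87 to 136 ± 6.29 TPM, log2 fold change 0.33), and 2 rises adjusted over the list alone. Gapdh was at 3535 ± 174 and 3707 ± 67.7 TPM. This list lost its call without WT replicate 1 (adjusted p = 0.0974), without KO replicate 2 (0.0759), and in 4 added alternatives, among them median-of-ratios scaling (0.0663). Smpdl3a, Tm7sf2, Prdx1 and Slc16a3 lost the call in 6, 7, 7 and 4 leave-one-out fits. By limma 0 of 23 fatty acid oxidation genes (camera adjusted p = 0.977), 0 of 39 oxidative phosphorylation genes (adjusted p = 0.319, but 0.0456 without a filter on low values and 0.0238 by directional fry) and 0 of 17 circadian clock genes (adjusted p = 0.782) passed. In these, Etfb was at 225 ± 17.9 and 213 ± 5.58 TPM, Atp5b at 1099 ± 69.9 and 1146 ± 21.5, and Bhlhe41 at 68.4 ± 5.25 and 68.5 ± 3.30.

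Cell cycle genes were called lower as a list by camera, by a small amount (37 tested, median log2 fold change -0.10, adjusted p = 0.000110; adjusted p = 0.646 with an estimated correlation, and 0.272 by directional fry). The 1 member past the threshold went the other way: Pcna, the sliding clamp of DNA replication, rose from 387 ± 28.2 to 464 ± 19.97 TPM (log2 fold change 0.26, adjusted p = 0.0383), a call lost in 6 leave-one-out fits with adjusted p up to 0.0996. Adjusted over the list alone 0 passed, and Cdk1 was at 88.9 ± 4.79 and 87.6 ± 3.47 TPM. Of 19 p53 targets, Mdm2 (log2 fold change -0.23) and Gdf15 (from 724 ± 110 to 513 ± 52.7 TPM, -0.49) fell and Sesn1 rose (0.27), and 16 did not pass, with the same counts adjusted over the list alone. Camera did not call this list (adjusted p = 0.0618), but called it lower in several alternatives. These were the fits without WT replicate 3 (camera adjusted p = 0.00899), WT replicate 4 (0.0482), KO replicate 4 (0.0470) or WT replicates 3 and 4 (0.00718). The others were median-of-ratios scaling (0.0297), rescaling over protein-coding genes (0.0240), the pseudogene covariate (0.0127) and the replicate number as a block (0.0279). The calls of Mdm2, Gdf15 and Sesn1 were lost in 7 of the leave-one-out fits each.

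Some matrix and stromal genes rose. Of 23 extracellular matrix remodeling genes, 5 rose, 0 fell and 18 did not pass; adjusted over the list alone, 9 rose and 2 fell (camera adjusted p = 0.00369; adjusted p = 0.646 with an estimated correlation). Thbs1, thrombospondin 1, rose from 1527 ± 84.0 to 1953 ± 52.3 TPM (log2 fold change 0.36, SE 0.047, adjusted p = 0.00780), Tgfbi from 9.93 ± 1.35 to 16.1 ± 0.444 TPM (0.65), Adamts1 from 26.6 ± 0.931 to 34.1 ± 1.46 TPM (0.34) and the protease Mmp14 from 161 ± 7.97 to 194 ± 5.44 TPM (0.26). Of 8 stromal markers tested, 4 rose, 0 fell and 4 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.00275; adjusted p = 0.646 with an estimated correlation). Only 6 of the 8 had a fold change above 0, and the list had a median of 0.25 and a lower mean of 0.17. Acta2, smooth muscle actin, rose from 1241 ± 61.1 to 1700 ± 38.5 TPM (log2 fold change 0.45, SE 0.043, adjusted p = 0.00170), Pdgfrb from 27.4 ± 1.34 to 37.3 ± 1.26 TPM (0.43), Col1a1 from 1534 ± 76.2 to 1873 ± 54.0 TPM (0.29) and Col3a1 from 311 ± 11.8 to 393 ± 35.5 TPM (0.34). Col1a1 lost the call without KO replicate 4 (adjusted p = 0.0573), Col3a1 in 4 leave-one-out fits (adjusted p up to 0.0768) and Mmp14 in 3 (up to 0.0708). The matrix list was not called without WT replicates 3 and 4 (adjusted p = 0.0549).

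Neutrophil markers were called lower as a list by camera (8 tested, median log2 fold change -0.25, adjusted p = 0.0181; adjusted p = 0.646 with an estimated correlation, and 0.274 by directional fry), with 0 members past the threshold by limma and 2 falls adjusted over the list alone. S100a9 was at 133 ± 24.6 and 116 ± 20.8 TPM and S100a8 at 58.6 ± 11.98 and 58.7 ± 12.9. The list lost its call without KO replicate 3 (adjusted p = 0.141), without WT replicates 3 and 4 (0.0549), under median-of-ratios scaling (0.0558), without a filter on low values (0.274) and with TPM over 5 required (0.105). Monocyte (7 tested, adjusted p = 0.977), osteoclast (6 tested, adjusted p = 0.977) and progenitor markers (8 tested, adjusted p = 0.988) were not called. The monocyte median was -0.04, with a mean of 0.07 and a test pointing up, and the osteoclast and progenitor medians and means were above 0 with tests pointing down. Adjusted over the list alone, 0 monocyte markers passed, 2 osteoclast markers rose and 2 fell, and 1 progenitor marker rose and 1 fell. Among them Acp5 rose from 12.5 ± 2.29 to 18.9 ± 1.91 TPM (log2 fold change 0.57) and Erg, also an endothelial factor, from 1.115 ± 0.153 to 2.02 ± 0.372 TPM (0.51), each lost in 7 leave-one-out fits, and Fn1 was at 834 ± 96.8 and 978 ± 101 TPM. Dendritic cell, B cell, T and NK cell, mast cell and basophil, and erythroid lists had fewer than 5 tested members and no list test. Of these, Itgax (0.49) and Il6ra (0.36) rose, calls lost in 6 and 7 leave-one-out fits, and Ebf1 (11.9 ± 0.549 and 11.9 ± 1.30 TPM), Cd4 (21.9 ± 1.33 and 19.98 ± 2.52) and Hbb-bs (9.63 ± 8.54 and 4.84 ± 4.24) did not pass.

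Lists that follow RNA quality were not called. Mitochondrially encoded genes (13 tested, adjusted p = 0.977) held 0 calls by limma, with mt-Co1 at 2490 ± 375 and 2703 ± 139 TPM, although the list was called without WT replicate 4 (adjusted p = 0.00934) and without WT replicates 3 and 4 (0.0119). Its median (0.03) and mean (0.01) were above 0 and its test pointed down. Replication-dependent histone genes (5 tested, adjusted p = 0.977) held 0 calls by limma and 1 rise adjusted over the list alone, with a median of -0.03, a mean of 0.01, and Hist1h1c at 114 ± 17.3 and 145 ± 4.95 TPM. Of 59 ribosomal protein genes (adjusted p = 0.977), Rps23 fell from 2515 ± 111 to 1841 ± 41.6 TPM (log2 fold change -0.45, SE 0.042, adjusted p = 0.00165) and 58 did not pass, with the same counts adjusted over the list alone, including Rplp1 at 6365 ± 577 and 6662 ± 237 TPM. Rps23 has processed pseudogenes up to 97.9% identical, and the protein-coding Gm5148 is 100% identical over 427 bases, so its value is uncertain. The best matches, Gm14633, Gm8624 and Gm5148, had mean TPM of 8.27, 7.91 and 0.81 over all libraries. Reads moved to these genes are too few to account for the fall of Rps23, and further matches were not examined. Xist lay between 55.8 and 81.8 TPM in the 8 libraries and Ddx3y reached at most 0.18 TPM, so sex did not differ between the groups by these genes.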

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

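A library was set apart when its gap to the nearest of the other 3, divided by the range of its group, passed Dixon's 95% critical value, which chance gives in about 5% of groups. Of 232 groups of 4 examined, 13 held such a library, against 11.6 by chance. WT replicates 1 and 2 had 3 of these each, WT replicate 3 and KO replicate 3 had 2 each, and KO replicate 4 had 0. No explanation was tested for them.

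Higher than the rest of its group was WT replicate 2 for Cxcl2 (11.26 TPM, others 6.33 to 7.15), Ier2 (21.99, others 19.65 to 19.89) and Cdk1 (96.1, others 86.35 to 86.88). WT replicate 1 was higher for Tm7sf2 (11.25 TPM, others 9.94 to 10.07), C1qa (233.65, others 201.43 to 206.61) and Gas6 (116.51, others 104.14 to 105.79). WT replicate 3 was higher for Bst2 (851.96 TPM, others 748.08 to 765.69) and Il1b (0.4, others 0.21 to 0.24). KO replicate 1 was higher for Pcna (493.7 TPM, others 450.21 to 457.39) and KO replicate 3 for Plac8 (70.61, others 39.77 to 44.5). Lower than the rest was WT replicate 4 for Rplp1 (5511.34 TPM, others 6519.32 to 6715.48), KO replicate 2 for Stab1 (41.63, others 46.88 to 47.74) and KO replicate 3 for Ighm (2.72, others 4.21 to 4.41). Of these genes Cxcl2, C1qa, Gas6 and Stab1 stayed called in every leave-one-out fit.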

How the results depend on the processing

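None of the 71 named genes past the threshold changed the sign of its fold change in an alternative that tested it, although quantile normalization set Ctsb to 0 by construction. Of these, 35 kept adjusted p under 0.05 in all 8 leave-one-out fits and 32 in all alternatives, among them Smarcd1, Lyz2, Lyz1, Siglec1, Cxcl2 and C1qa. Smarcd1 stayed called throughout (adjusted p up to 0.0364). A smaller pseudocount, no trend, robust variance and library weights gave 780, 702, 818 and 830 called genes, within 1.5 times of 782. The stricter filter, the other scalings, robust variance, library weights, the pseudogene covariate and the fit without WT replicates 3 and 4 were chosen after seeing the data.

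Without a filter on low values, 364 genes were called (292 rose, 72 fell), with 41 list members and 45 named genes; 27510 genes then shared the adjustment. With the replicate number as a block, 209 genes were called (146 rose, 63 fell), 41 list members and 40 named genes. Same-numbered libraries deviated with correlations between -0.113 and 0.0124, and 0 of 4 WT libraries matched best its own number. No pairing by number was thus seen, but so few libraries cannot exclude one, and the labels do not say. Leaving out 1 library gave 156 to 679 called genes (120 to 532 rose, 36 to 235 fell), 30 to 79 list members, 37 to 66 named genes and 11 to 14 lists; fewer samples enter each fit. Median-of-ratios scaling gave 406 falls, quantile normalization 254, and the pseudogene share as covariate 299. Rescaling over protein-coding genes gave 1326 calls (484 fell) and 117 list members. Without WT replicates 3 and 4, 372 genes were called (201 rose), with 47 list members and 43 named genes; of these genes, 246 were among the 782. The cause of the scaling differences was not tested beyond the tests given under other observations.

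For lists, camera with an estimated correlation called 0 of 31, fry 7 by direction and 23 in either direction, against 12. Alternatives that need read counts (other count normalizations and count filters, count-based tests and the ranking of their fold changes) were not run on TPM, and a sex covariate was not needed. TPM keeps no depth, so precision at low values cannot be given; recovery at the smallest simulated fold was 32.8%.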

Other observations

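The tests of macrophage share, of the spread among stromal markers, of the summed lysozymes and of the lysozyme ratio were chosen after the results were seen, as were the lists of mesenchymal and endothelial genes and the scalings used.

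Other transcripts of non-hematopoietic cells were also higher in the Baf60a KO cultures, in lists picked from these data and so given as values only. The counts and adjusted p of their members follow from that choice in part and are no separate evidence for more such cells. Of 25 contractile and matrix genes of mesenchymal cells, 12 rose, 0 fell and 25 had a fold change above 0, with a median of 0.26. Actg2, smooth muscle gamma actin, rose from 158 ± 8.73 to 235 ± 7.26 TPM (limma adjusted p = 0.000894), Thbs2 from 158 ± 10.2 to 226 ± 10.4 TPM and Postn from 213 ± 12.1 to 293 ± 22.7 TPM. Tagln, at 925 ± 81.7 and 1038 ± 42.0 TPM, did not pass. Of 17 endothelial markers tested, 8 rose, 0 fell and 17 had a fold change above 0, with a median of 0.42. Mcam rose from 9.71 ± 0.718 to 15.4 ± 1.69 TPM (adjusted p = 0.00942), Pecam1 from 7.50 ± 0.546 to 11.8 ± 1.57 TPM (0.0144) and Plvap from 9.29 ± 1.21 to 14.6 ± 1.58 TPM (0.0192).

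Of 35 splits of the 8 libraries into 4 and 4, only the real one gave as many called genes (782, highest other 4). The same held for list members (75, highest other 0). A share of 1 in 35 is the smallest that these splits can give. The other splits mix the groups, so a real difference widens their spread and lowers their counts. A difference in culture or handling between the groups would give the same result. For lists, 1 split gave as many (12), but the highest other gave 10, and splits with 2 WT and 2 KO libraries on each side gave up to 8. The number of lists called by camera is thus weak evidence of a group difference.

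Of 8 stromal markers, 4 rose in Baf60a KO and 4 did not pass (camera adjusted p = 0.00275; adjusted p = 0.646 with an estimated correlation). The fold change was above 0 in 6 of the 8. A lower macrophage share with all other cell types raised alike would raise neutrophil and progenitor markers too. Yet the median of the stromal markers exceeded that of 10 neutrophil and progenitor markers by 0.347 (95% bootstrap interval 0.0303 to 0.598). This interval treats genes as independent and holds no spread between libraries, so it weighs only weakly against that reading. The estimated correlation was 0.26 in the whole stromal list, 0.39 in the neutrophil list and -0.03 in the progenitor list. A lower macrophage share with stromal cells alone raised would give the same difference, so it is not excluded. Scaling left the stromal median at 0.207 or above. A larger share of one stromal type stays open: the log2 fold changes of its markers spread more than in other splits (1 of 35 as large; statistic 55.1, highest other 22.6), with Cxcl12 at 232 ± 22.3 and 232 ± 38.7 TPM and Acta2 higher, but no table shows which cells carry each marker, and splits that mix the groups hold no change of share. A larger share of several stromal or endothelial types, or changed expression in stromal cells or macrophages, may also remain and was not tested.

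Lyz2 fell while Lyz1 rose. Reads moved to Lyz1 cannot account for the fall of Lyz2, since the summed TPM fell with a log2 fold change of -1.05 (95% interval -1.18 to -0.91): Lyz2 lost 2066 TPM and Lyz1 gained 5.16, a rise for which reads of Lyz2 assigned to Lyz1 are not excluded. Fewer macrophages would lower the other 23 identity genes, whose median was 0.175 (interval 0.1001 to 0.288 over bootstrap draws of genes). That interval treats genes as independent and holds no spread between libraries, while the estimated correlation of the whole identity list was 0.484. The KO to WT ratio of Lyz2 was 0.483 (interval 0.440 to 0.529), which holds 0.5. A candidate explanation is thus that 1 of 2 Lyz2 copies is replaced in the KO mice, as in a common myeloid Cre line. The labels do not give the allele, and an effect of Baf60a on Lyz2 transcription stays open.

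More genes rose than fell (78.4% of calls). Under median-of-ratios scaling the share of rises was 55.3%, and without WT replicates 3 and 4 it was 54.0%. It was 63.4% with quantile normalization, 63.5% rescaled over protein-coding genes and 63.1% with the pseudogene covariate. With 1 library left out it ran from 63.7% (without WT replicate 3) to 85.9% (without WT replicate 2). The excess of rises may come from the scaling of TPM and from WT replicates 3 and 4, and is not a firm property of the knockout.

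Gm44032 was listed at 0 in all KO libraries and between 14.6 and 32.0 TPM in WT, and Gm44227 at 0 in all WT libraries and between 2.60 and 3.78 TPM in KO. Both are processed pseudogenes, whose transcripts are 95.1% identical to Dedd over 162 bases and 92.6% identical to Cfl1 over 244 bases. Of 148 tested genes within 5 Mb of Smarcd1 or Lyz2, 14 (9.46%) were called, against 5.56% of the others (Fisher's exact test, two-sided, p = 0.0473, adjusted p = 0.0807 over 3 such comparisons).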
